A study of Homo sapiens with 4 samples.

How the data were processed

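RNA of hTERT-RPE1 cells was sequenced in 4 libraries, 2 labelled sgControl and 2 labelled sg53BP1. Per the labels' protocols, cells were grown in DMEM with 10% fetal bovine serum, total RNA was extracted with phenol and chloroform, 2 µg of it entered each library, and paired-end reads of 150 bp were generated on an Illumina instrument. Per the submitters' processing notes, HISAT2 2.1.0, Bowtie2 2.2.3 and HTSeq 0.6.0 were used with genome build hg19; which step each tool did, the annotation and the strand setting are not given in the sources used here. Without a stated strand, reads of overlapping and antisense genes cannot be told apart; genes taken by the rule for named genes that overlap another gene, small RNAs and processed pseudogenes aside, are listed in the report, and overlaps of other genes were not looked up.

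The authors deposited 1 table with the read count of each gene in each library, not normalized. The same deposited table holds the authors' comparison of the groups: a mean level as a signal value, a log2 fold change and its standard error on the log2 scale, a test statistic as a score, and p-values with adjusted p-values. Per the file headers the column names are those of a DESeq2 results table, but the tool is not stated there. Among 11943 genes with 100 or more counts, the sign of the authors' log2 fold change equalled that of control over knockout for 99.56%, so that sign was turned before any comparison. The authors' adjusted p was missing for 5605 genes and under 0.05 for 867, of which 500 were higher in the sgControl columns and 367 in the sg53BP1 columns. Each count column was matched to its sample by the sample's description in the labels.

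The table had 20050 rows for 19653 Ensembl identifiers. Rows of the 172 identifiers that carried several symbols held identical counts, and 397 repeats were removed. All 19653 identifiers matched the name table and GENCODE release 29, which is on another genome build than the counts; it was used for gene types (15482 protein-coding) and for which genes overlap or neighbour each other, and no coordinates were taken from it. Each listed gene had at least 1 count over the 4 libraries. Library totals lay between 16654411 and 18164086 counts, so that a floor of 3 counts corresponded to 0.165 to 0.180 CPM in a library. Floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Where a group had 1 to 3 counts, the ratio of the groups is given with a 95% interval from the exact binomial (Clopper-Pearson) interval of the counts.

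Groups were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust dispersion, group as the only term) and Benjamini-Hochberg adjustment over 13140 tested genes, with a threshold of 0.05. TMM factors lay between 0.9961 and 1.01. The biological coefficient of variation was 0.18, and the median log2 fold change of all tested genes was −0.02. Standard errors were back-calculated from the F statistic. Levels are CPM scaled by TMM, as mean ± SD of 2 libraries. The SD of the 2 libraries labelled sgControl was often the larger, while the test estimated 1 spread for each gene over both groups.

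A total of 34 gene lists was fixed before the data were examined, as were the alternatives, the design and the rule for named genes. Lists with at least 5 measured members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 33 lists. Alternatives were a correlation estimated per list and the rotation test fry, whose directional p tests whether members move one way on balance and whose mixed p tests change in either direction. The correlation was estimated from 2 libraries per group, which leaves few degrees of freedom, so that alternative had little power to call a list. The gap between libraries of a group was the median difference of the members' log2 CPM (prior count 2), ranked among 10000 random lists drawn from 20 bins of expression. Named genes were TP53BP1; the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold, with at least 5 CPM in the higher group, no overlap between groups and a gene symbol that is not a clone name; and up to 4 called members with the smallest adjusted p of each list that had 3 called members or passed camera. Of the genes that met this rule, 1 is not reported here. Genes named outside this rule are said to be chosen after their values were seen.

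Other settings tried were DESeq2 size factors, library totals without TMM, no low-count filter, a mean of at least 5 CPM, the DESeq2 1.42.0 Wald test, limma-voom, an absolute log2 fold change of at least 1, the replicate number as a block, and leaving out each library in turn. Where a library was left out, the lone library of its group was assumed to vary like the other group. List tests with DESeq2 used cameraPR on the Wald statistic, and those with voom used its weights. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

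The steps were tested on simulated counts drawn for 13140 genes from the means and depths of this comparison, of which 12950 passed the low-count filter. At a log2 fold change of 1, edgeR recovered 61 of 100 changed genes, and at 2 it recovered 92 of 100, with 14 false calls among 12904 unchanged genes. A list shifted by 0.5 on the log2 scale gave a camera p of 6.18e-17, and 0 of the 32 other lists were called. Genes were drawn independently of each other, with 1 dispersion per gene for both groups. The false calls therefore do not measure errors for list members that move together or for groups of unequal spread, as here.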

Results

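RNA levels were measured by RNA sequencing in hTERT-RPE1 cells, a human retinal pigment epithelial line immortalised with telomerase. Cells that had received a lentiviral CRISPR-Cas9 vector with a guide RNA against 53BP1, labelled sg53BP1, were set against cells that had received the Cas9 vector without a guide, labelled sgControl. 53BP1, encoded by TP53BP1, is a chromatin-binding protein that directs the repair of DNA double-strand breaks towards end joining and takes part in p53 signalling. Each group had 2 libraries. Total gene counts were 16654411 and 16830331 in the libraries labelled sgControl and 18164086 and 17883332 in those labelled sg53BP1. Between 16538 and 17171 genes had at least 1 count in a library. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

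The libraries labelled sgControl lay further apart than those labelled sg53BP1. Levels are given in CPM, a gene's count relative to the scaled total of its library. Across genes above 5 CPM, log2 levels of the sgControl pair correlated with Pearson r = 0.9551 and 374 genes differed more than 2-fold, whereas the sg53BP1 pair gave r = 0.9937 and 1 such gene. Pairs from different groups gave r between 0.9525 and 0.956, with 424 to 511 such genes. These correlations are across genes, which are not independent replicates. The chi-square statistic per degree of freedom was 56.8 for the sgControl pair and 7.28 for the sg53BP1 pair, so neither pair agreed within sampling noise. The test below estimated 1 spread for both groups, and the number of genes it called rests on that.

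TP53BP1, the targeted gene, was not lower in the libraries labelled sg53BP1. Its counts were 431 and 594 in the libraries labelled sgControl and 1743 and 1516 in those labelled sg53BP1, or 30.7 ± 6.64 CPM (SD, n = 2) and 90.3 ± 8.61 CPM (SD, n = 2). TP53BP1 (ENSG00000067369) was thus 2.94-fold higher where the knockout is labelled, a log2 fold change of 1.56 with a standard error of 0.18 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00224). In the authors' deposited table the log2 fold change of TP53BP1 was −1.58 with a standard error of 0.20 and an adjusted p of 9.75e-13, with the sgControl columns lower once its sign, control over knockout, is read. Without replicate 1 or replicate 2 labelled sg53BP1 the difference was 1.46 and 1.66 on the log2 scale and the edgeR adjusted p rose to 0.144 and 0.106. Reads of TP53BP1 can be shared with TUBGCP4, which overlaps it in GENCODE release 29, and an edited gene may still be transcribed. Directions below are therefore given as the labels name the libraries, and every direction would turn if the labels of the groups were exchanged.

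**Figure D1:**
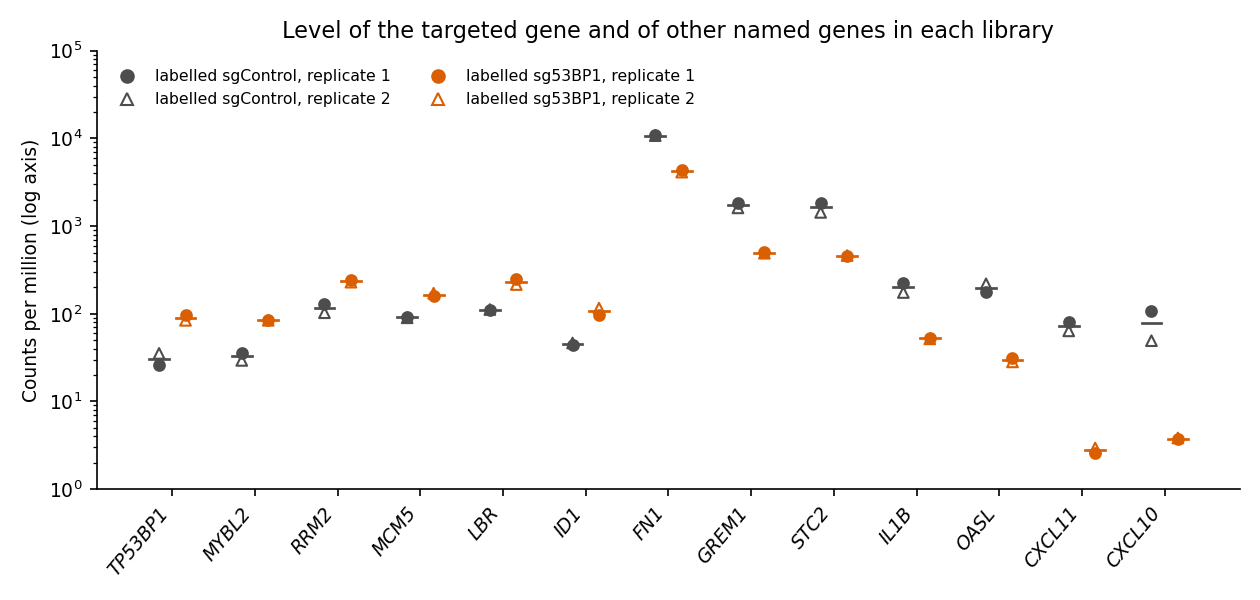
Level of TP53BP1 and of 12 other named genes in each library, in CPM on a log axis. Circles are replicate 1 and triangles replicate 2, grey for libraries labelled sgControl and orange for those labelled sg53BP1, and bars are group means. TP53BP1 lies higher in both libraries labelled sg53BP1 (means 30.7 and 90.3 CPM), as do MYBL2, RRM2, MCM5, LBR and ID1, while FN1, GREM1, STC2, IL1B, OASL, CXCL11 and CXCL10 lie lower there.

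Of 13140 genes tested, 667 passed an adjusted p of 0.05 (edgeR quasi-likelihood test), 272 of them higher and 395 lower in the libraries labelled sg53BP1. An absolute log2 fold change of at least 1 was reached by 368 of these genes, 161 higher and 207 lower, and 641 of the 667 were protein-coding. All 667 had the same direction in the authors' deposited table once its sign was turned, and 649 also passed 0.05 there. Without sgControl replicate 1 or 2 the count was 3358 and 2493. Without sg53BP1 replicate 1 or 2 it was 5 in each case, since the spread then came from the distant sgControl pair alone. CXCL11 kept its call in both of these last fits and OASL in the first, while all other named genes lost theirs. Besides TP53BP1, the genes named below that overlap another annotated gene in GENCODE release 29, with which they can share reads, were MBNL3, LRRN1, XK, CXCL11, CXCL10, MMP1, C1QTNF1, ATP6V0D2, PHLDA3, RRM2, GINS2, TNC, MMP2, ZEB1, ZEB2, CD44, GREM1, INHBA, STARD4, VEGFA, P4HA2, SLC7A11, CEBPB, DUSP1, LGR5, WNT5B, DNMT1, ND4, GABARAPL1, CTSB, WIPI1, NTM, THY1 and PDGFRA. Overlaps of genes chosen after their values were seen were not looked up.

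**Figure D2:**
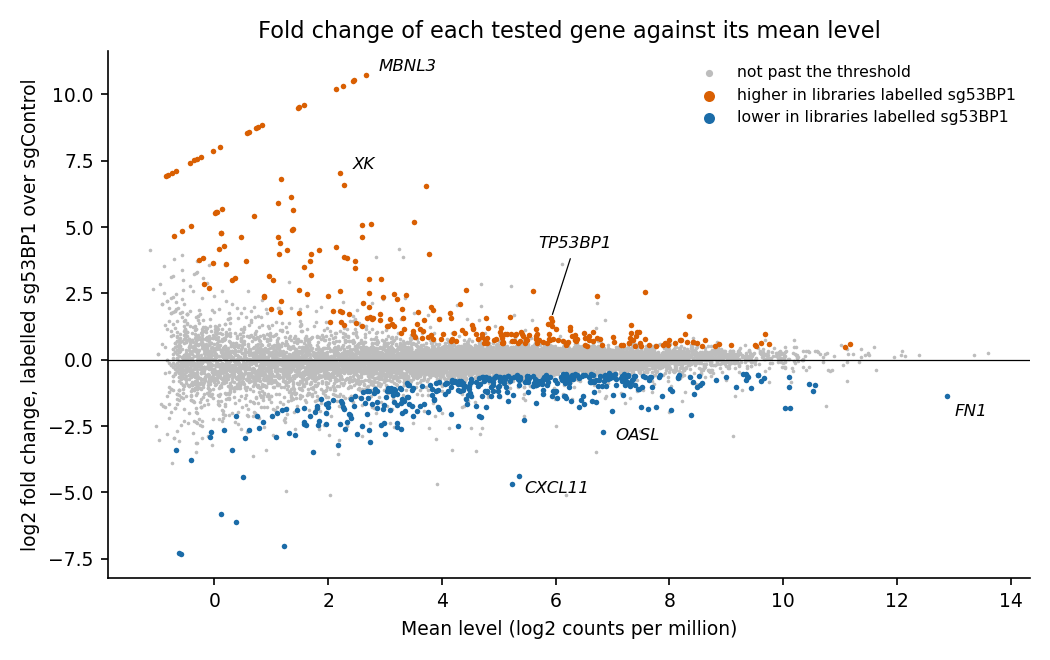
Log2 fold change of each of 13140 tested genes, libraries labelled sg53BP1 over sgControl, against the mean level in log2 CPM. Orange points are the 272 genes that passed an adjusted p of 0.05 upward and blue points the 395 downward. The rising line at the upper left is formed by genes with no count in either library labelled sgControl, such as MBNL3, whose fitted fold changes depend on the prior count.

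The largest increases in the libraries labelled sg53BP1, where TP53BP1 was the higher, were in genes with no count in either library labelled sgControl. MBNL3, a muscleblind-like RNA-binding protein, had 241 and 203 counts against 0 and 0, at least 137-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 3.06e-04). MFAP5, a microfibril-associated glycoprotein of the elastic matrix, was at least 119-fold higher, with 194 and 192 counts. LRRN1, a leucine-rich repeat membrane protein, was at least 117-fold higher, and CD180, a Toll-like receptor homologue best known from B cells, at least 103-fold higher. The kinase NRK was at least 94.4-fold higher, the histone variant H2AJ at least 62.6-fold, the adhesion protein MPZL2 at least 59.2-fold and KLHDC7A at least 58.0-fold. XK, a membrane transport protein of red cells, had 2 and 0 counts against 149 and 170, a ratio of 148 with a 95% counting interval of 40.5 to 1224. COL6A6, a collagen VI chain, had 0 and 3 counts against a total of 336, a ratio of 104 with an interval of 35.2 to 505. MBNL3, LRRN1 and XK overlap other annotated genes, among them RAP2C-AS1 and SUMF1 for the first pair, and the strand of the counts is not given in the sources used here. In all, 23 of the genes called higher had no count in either library labelled sgControl, while only IFNL1 and BCL2A1, chosen after their values were seen, were called lower with no count in the libraries labelled sg53BP1.

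The largest decreases in the libraries labelled sg53BP1 included a pair of interferon-inducible chemokines. CXCL11, a ligand of the receptor CXCR3, fell from 72.0 ± 11.5 to 2.77 ± 0.244 CPM (SD, n = 2 each), a log2 fold change of −4.70 with a standard error of 0.19 (edgeR adjusted p = 2.66e-05). CXCL10, a ligand of the same receptor, fell from 77.8 ± 40.2 to 3.77 ± 0.0903 CPM, a log2 fold change of −4.36 with a standard error of 0.53 (edgeR adjusted p = 0.0475). Both chemokine genes overlap ART3. Both were higher in sgControl replicate 1 than in replicate 2, CXCL11 at 80.1 and 63.9 CPM and CXCL10 at 106 and 49.3 CPM. The list of interferon-stimulated genes, given below, went the other way and stood higher in replicate 2. OASL, an oligoadenylate synthetase-like antiviral protein, fell from 198 ± 30.2 to 29.9 ± 2.34 CPM and was 6.63-fold lower. The interstitial collagenase MMP1 was 11.1-fold lower, the matrix protein ABI3BP 9.30-fold, the netrin NTNG2 8.62-fold and the secreted C1QTNF1 6.95-fold. ATP6V0D2, a subunit of the vacuolar proton pump, was 6.89-fold lower, the BMP-binding protein BMPER 6.31-fold and VAT1L 6.12-fold. Without sgControl replicate 1 the log2 fold changes fell in size to −3.68 for CXCL10, −2.81 for MMP1, −2.34 for ABI3BP and −2.01 for BMPER, and without sgControl replicate 2 that of MMP1 was −4.13. With limma-voom CXCL10 (adjusted p = 0.122), ABI3BP (adjusted p = 0.109) and BMPER (adjusted p = 0.0501) lost their calls, as did CXCL10 with DESeq2 size factors (adjusted p = 0.0526) and MMP1 with the replicate number as a block (adjusted p = 0.0602).

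The list of DNA replication genes shifted upward in the libraries labelled sg53BP1. All 40 E2F and S-phase genes had a positive log2 fold change, with a median of 0.62, and 16 rose while none fell (34 and 0 adjusted over the list alone). RRM2, the small subunit of ribonucleotide reductase, rose from 115 ± 17.7 to 237 ± 10.2 CPM (SD, n = 2 each), 2.05-fold. The replicative helicase subunit MCM5 rose 1.81-fold, the helicase loader CDC6 1.74-fold and GINS2, a part of the active helicase, 1.96-fold. The list passed the camera test (adjusted p = 2.06e-16), and its adjusted p was 0.56 with an estimated correlation. Of 39 genes of G2 and mitosis, 2 rose and none fell (2 and 0 adjusted over the list alone), with a median of 0.27. These were MYBL2, a transcription factor of the cell cycle, which rose 2.57-fold from 32.8 ± 4.77 to 84.3 ± 0.0702 CPM, and the proliferation marker MKI67, which rose 1.47-fold. The mitotic list passed camera (adjusted p = 2.35e-05; adjusted p = 0.643 with an estimated correlation), and without sgControl replicate 2 it did not (median 0.13, adjusted p = 0.0961). Its median was 0.49 without sgControl replicate 1. GINS2 and MKI67 lost their calls with the replicate number as a block (adjusted p = 0.0502 and 0.0932). Histone genes, listed as replication-dependent although H1-10 is not, had no called member among 12 and a median of −0.82 (camera adjusted p = 0.254). Their median level was 1.34 log2 units higher in sgControl replicate 2 than in replicate 1. The median log2 fold change of this list was −1.32 without sgControl replicate 1 and −0.012 without sgControl replicate 2.

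DNA repair and chromatin lists also shifted upward in the libraries labelled sg53BP1. Among 24 genes of the 53BP1 pathway and non-homologous end joining, TP53BP1 itself was the only called member (1 higher and 0 lower, also adjusted over the list alone), and the median log2 fold change was 0.23. The list includes the targeted gene and was not tested without it. This list passed camera (adjusted p = 0.0212; adjusted p = 0.56 with an estimated correlation), but not without sgControl replicate 2 (adjusted p = 0.108) or sg53BP1 replicate 1 (adjusted p = 0.0769). Of 34 homologous recombination genes 29 had a positive log2 fold change and none passed alone (0 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 5.54e-04; adjusted p = 0.56 with an estimated correlation; median 0.253 without sgControl replicate 1). Of 31 genes of heterochromatin and DNA methylation, 4 rose and none fell (6 and 0 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 7.25e-04; adjusted p = 0.56 with an estimated correlation). LBR, the lamin B receptor of the inner nuclear membrane, rose 2.08-fold from 112 ± 0.0496 to 232.5 ± 24.0 CPM. The maintenance DNA methyltransferase DNMT1 rose 1.60-fold, the nuclear lamin LMNB1 1.73-fold and the de novo methyltransferase DNMT3B 1.98-fold. These 3 lost their calls with the replicate number as a block (adjusted p = 0.0578, 0.0529 and 0.0881). Among 39 targets activated by p53 none rose and 3 fell (0 and 4 adjusted over the list alone), with a median of −0.12 (camera adjusted p = 0.181). Among those that fell, PHLDA3 was 1.73-fold and PLK2 1.46-fold lower. PLK2 lost its call with DESeq2 size factors (adjusted p = 0.0517), library totals (adjusted p = 0.05) and the replicate number as a block (adjusted p = 0.128). The p53 list was 0.36 log2 units higher at the median in sgControl replicate 2 than in replicate 1, and it passed camera downward without sgControl replicate 1 (median −0.31, adjusted p = 7.17e-05) and with the DESeq2 Wald test (median −0.11, adjusted p = 0.0299) but not without sgControl replicate 2 (median 0.21, adjusted p = 0.12).

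The list of TGF-beta targets shifted downward in the libraries labelled sg53BP1. Of 26 measured, 2 rose and 7 fell (3 and 8 adjusted over the list alone), with a median log2 fold change of −0.46 (camera adjusted p = 0.00524; adjusted p = 0.56 with an estimated correlation; median −0.297 without sgControl replicate 2). GREM1, a secreted antagonist of bone morphogenetic proteins, fell 3.48-fold from 1732 ± 166 to 497 ± 9.21 CPM (SD, n = 2 each). INHBA, the activin A subunit, fell 3.69-fold. ID1, a transcriptional inhibitor induced by bone morphogenetic proteins, and SMAD6, an inhibitor of the same pathway named after its values were seen, were the members that rose, ID1 by 2.38-fold from 45.0 ± 2.02 to 107 ± 12.8 CPM. Counts of INHBA can include reads of the antisense gene INHBA-AS1.

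Matrix genes went both ways. Of 33 collagens and matrix proteins, 2 rose and 7 fell (2 and 12 adjusted over the list alone), with a median log2 fold change of −0.39 but a mean of 0.01. The mean includes the fitted values of MFAP5 and COL11A1, and the median was also −0.39 with MFAP5 at its bound. FN1, which encodes fibronectin, fell 2.55-fold from 10792 ± 40.8 to 4240 ± 159 CPM (SD, n = 2 each), and the matricellular protein TNC fell 2.27-fold. COL11A1, a fibrillar collagen chain, rose from 0.150 ± 0.0410 to 4.79 ± 1.91 CPM. The list passed camera downward (adjusted p = 0.0149; adjusted p = 0.56 with an estimated correlation), but not without sgControl replicate 1 (median −0.202, adjusted p = 0.064), without sg53BP1 replicate 2 (adjusted p = 0.104) or without the low-count filter (median −0.163, adjusted p = 0.184). Among 21 mesenchymal genes, 2 rose and 4 fell (3 and 7 adjusted over the list alone), with a median of −0.43 (camera adjusted p = 0.0516, and 0.0346 without sgControl replicate 2, 0.0167 with the DESeq2 Wald test and 0.0433 with limma-voom). The gelatinase MMP2 fell 1.95-fold and the hyaluronan receptor CD44 1.60-fold, while the related repressors of epithelial genes ZEB1 and ZEB2 went apart, ZEB1 rising 1.89-fold and ZEB2 falling 1.78-fold; both overlap antisense genes. With the replicate number as a block CD44 and ZEB2 lost their calls (adjusted p = 0.062 and 0.054). Fibroblast markers, listed as another cell type, moved with these groups: of 5 measured, none rose and 2 fell (0 and 4 adjusted over the list alone), THY1 by 1.81-fold and PDGFRA by 3.74-fold, with a median of −0.82 (camera adjusted p = 0.00898; adjusted p = 0.56 with an estimated correlation). COL1A1, FAP and PDGFRB among them also stand on the matrix or mesenchymal list, and the call of the list was lost without sg53BP1 replicate 1 (adjusted p = 0.0727) and without the low-count filter (median 0.02, adjusted p = 0.747). PDGFRA lost its call with the replicate number as a block (adjusted p = 0.0932).

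The list of inflammatory genes shifted downward in the libraries labelled sg53BP1. Of 26 NF-kB targets and secreted factors measured, none rose and 4 fell (0 and 8 adjusted over the list alone), with a median log2 fold change of −0.65 (camera adjusted p = 1.47e-04; adjusted p = 0.56 with an estimated correlation; median −0.43 at a mean of at least 5 CPM and −1.143 without the low-count filter). The cytokine IL1B fell 3.83-fold from 200.5 ± 36.3 to 52.4 ± 0.815 CPM (SD, n = 2 each), the growth factor CSF2 5.25-fold and the NF-kB subunit RELB 2.40-fold, beside MMP1. RELB lost its call with the replicate number as a block (adjusted p = 0.0813). The list stood 0.79 log2 units lower at the median in sgControl replicate 2 than in replicate 1.

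Of 43 interferon-stimulated genes measured, OASL alone passed (0 higher and 1 lower, also adjusted over the list alone), and the median log2 fold change was −0.43 (camera adjusted p = 0.387). The list passed downward with the DESeq2 Wald test (median −0.41, adjusted p = 9e-04). Its median was 0.142 with limma-voom and 0.096 with the replicate number as a block (adjusted p = 0.317 and 0.527). The libraries labelled sgControl stood far apart: the median member was 2.03 log2 units higher in replicate 2 than in replicate 1, above all of 10000 random lists matched on expression, whereas the sg53BP1 libraries differed by −0.13. All 43 members were higher in sgControl replicate 2 than in both libraries labelled sg53BP1, and 32 were lower in sgControl replicate 1 than in both. IFI6, an interferon-induced mitochondrial protein chosen after its values were seen, had 54.4 and 1840 CPM in the libraries labelled sgControl and 673 and 721 CPM in the others. The left-out library set the list's direction, with a median of −1.14 without sgControl replicate 1 (camera adjusted p = 4.9e-19) and 1.09 without replicate 2 (camera adjusted p = 7.7e-10). MHC class I presentation genes moved in the same way between the libraries labelled sgControl, with a gap of 1.53. Of 17 measured, 1 fell (0 and 1 adjusted over the list alone), the peptide-loading factor TAPBP by 1.58-fold (adjusted p = 0.0938 with the replicate number as a block), with a median of −0.73 (camera adjusted p = 0.0212; adjusted p = 0.745 with an estimated correlation). Without sgControl replicate 1 that median was −1.18, without sgControl replicate 2 it was 0.24 (adjusted p = 0.164), and without sg53BP1 replicate 1 or 2 the adjusted p was 0.0689 and 0.0601.

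**Figure D3:**
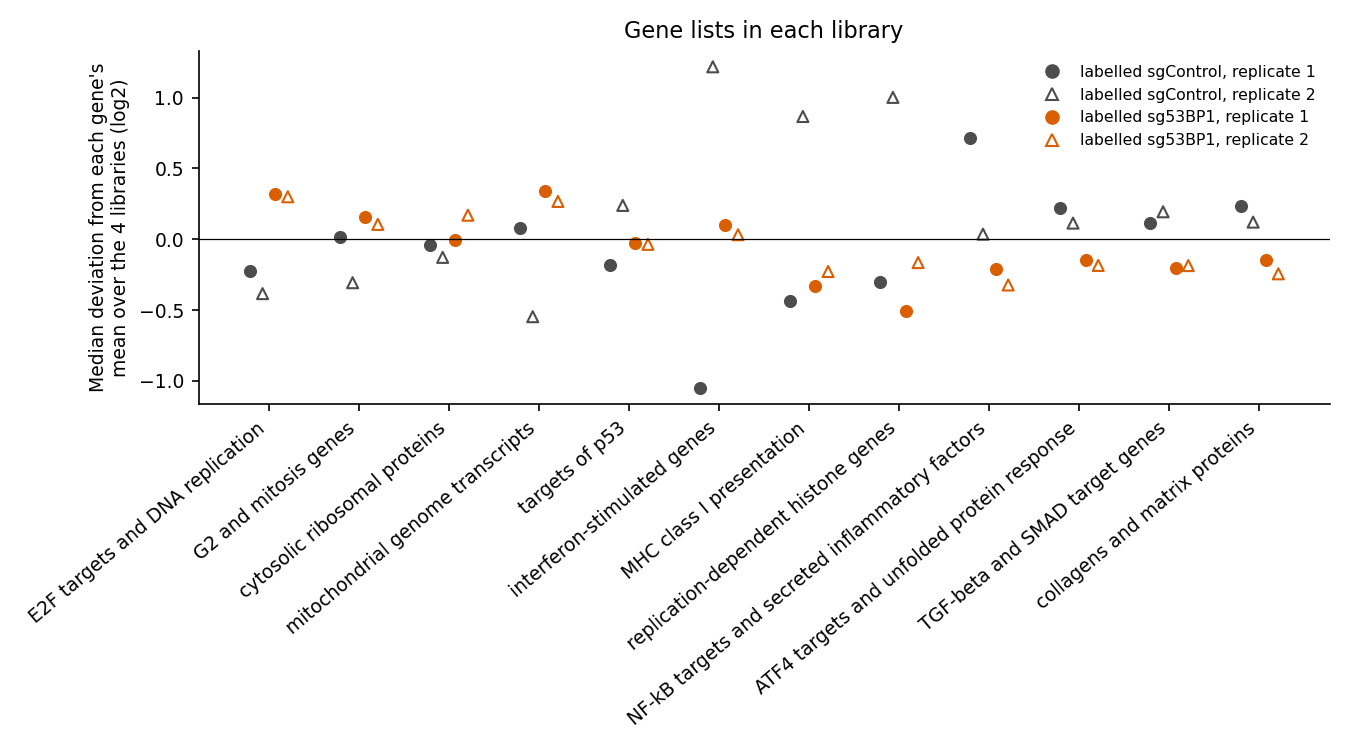
Median deviation of the members of 12 gene lists from each gene's mean over the 4 libraries, in log2 units, for each library. Grey marks are libraries labelled sgControl and orange those labelled sg53BP1, with circles for replicate 1 and triangles for replicate 2. The interferon-stimulated genes lie at −1.05 and 1.22 in the libraries labelled sgControl and at 0.10 and 0.03 in the others, while the E2F targets lie at −0.22 and −0.38 against 0.32 and 0.30.

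Several stress and metabolic lists shifted downward in the libraries labelled sg53BP1. Of 32 ATF4 and unfolded protein response genes, 1 rose and 5 fell (1 and 8 adjusted over the list alone), with a median log2 fold change of −0.43 (camera adjusted p = 5.54e-04; adjusted p = 0.56 with an estimated correlation; median −0.223 without sgControl replicate 1). The secreted glycoprotein STC2 fell 3.53-fold from 1632 ± 280 to 462 ± 0.345 CPM (SD, n = 2 each), the transcription factors XBP1 and CEBPB fell 1.84-fold and 1.80-fold, and the cystine transporter SLC7A11 rose 1.65-fold (adjusted p = 0.0525 with the replicate number as a block). Of 33 glycolytic and HIF target genes, none rose and 5 fell (0 and 7 adjusted over the list alone), with a median of −0.22 (camera adjusted p = 0.0138; adjusted p = 0.626 with an estimated correlation; without sgControl replicate 2 median −0.024, adjusted p = 0.226). The glucose transporter SLC2A3 fell 2.32-fold, NDRG1 2.44-fold, the angiogenic factor VEGFA 2.06-fold and the collagen prolyl hydroxylase subunit P4HA2 1.94-fold. Of 28 lysosome and autophagy genes, none rose and 4 fell (1 and 4 adjusted over the list alone), with a median of −0.22 (camera adjusted p = 0.00443; adjusted p = 0.56 with an estimated correlation; without sgControl replicate 2 median −0.072, adjusted p = 0.108; without sg53BP1 replicate 1 median −0.145). These were GABARAPL1, the cathepsins CTSL and CTSB, and WIPI1, at 1.72-fold, 1.53-fold, 1.44-fold and 1.56-fold lower. All 4 lost their calls with the replicate number as a block (adjusted p = 0.0582, 0.0767, 0.104 and 0.107). CTSB and WIPI1 also lost them with DESeq2 size factors (adjusted p = 0.0513 each), and WIPI1 with library totals (adjusted p = 0.0526) and limma-voom (adjusted p = 0.0588). Of 24 sterol synthesis genes the lipid transfer protein STARD4 alone was called, 1.72-fold lower (adjusted p = 0.0814 with the replicate number as a block; 0 and 1 adjusted over the list alone), with a list median of −0.24 (camera adjusted p = 0.0268; adjusted p = 0.56 with an estimated correlation). That call was lost without sgControl replicate 1 (adjusted p = 0.114), sgControl replicate 2 (adjusted p = 0.0712) or sg53BP1 replicate 1 (adjusted p = 0.151).

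The lists of ribosomal proteins and mitochondrial transcripts shifted upward in the libraries labelled sg53BP1, with few called members. All 41 ribosomal protein genes had a positive log2 fold change, with a median of 0.18, and none passed alone (0 adjusted over the list alone; camera adjusted p = 1.5e-04; adjusted p = 0.643 with an estimated correlation; median 0.276 without sg53BP1 replicate 1 and 0.076 without sg53BP1 replicate 2). Of 13 transcripts of the mitochondrial genome ND4, which overlaps ND4L, was called, 1.51-fold higher (adjusted p = 0.107 with the replicate number as a block; 2 higher and 0 lower adjusted over the list alone), with a median of 0.59 (camera adjusted p = 5.46e-04; adjusted p = 0.643 with an estimated correlation). Mitochondrial transcripts took 1.74% of the counts in sgControl replicate 2 against 2.73% in replicate 1 and 2.93% and 2.87% in the libraries labelled sg53BP1, and without sgControl replicate 2 the list did not pass (median 0.23, camera adjusted p = 0.085). Of 36 primary cilium genes none passed alone (0 adjusted over the list alone), with a median of −0.11 (camera adjusted p = 0.0444; adjusted p = 0.626 with an estimated correlation). The cilium call was lost with the DESeq2 Wald test (adjusted p = 0.158) and without sg53BP1 replicate 2 (adjusted p = 0.184), and its median was 0.05 without sgControl replicate 1 (adjusted p = 0.725) and −0.23 without sgControl replicate 2.

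**Figure D4:**
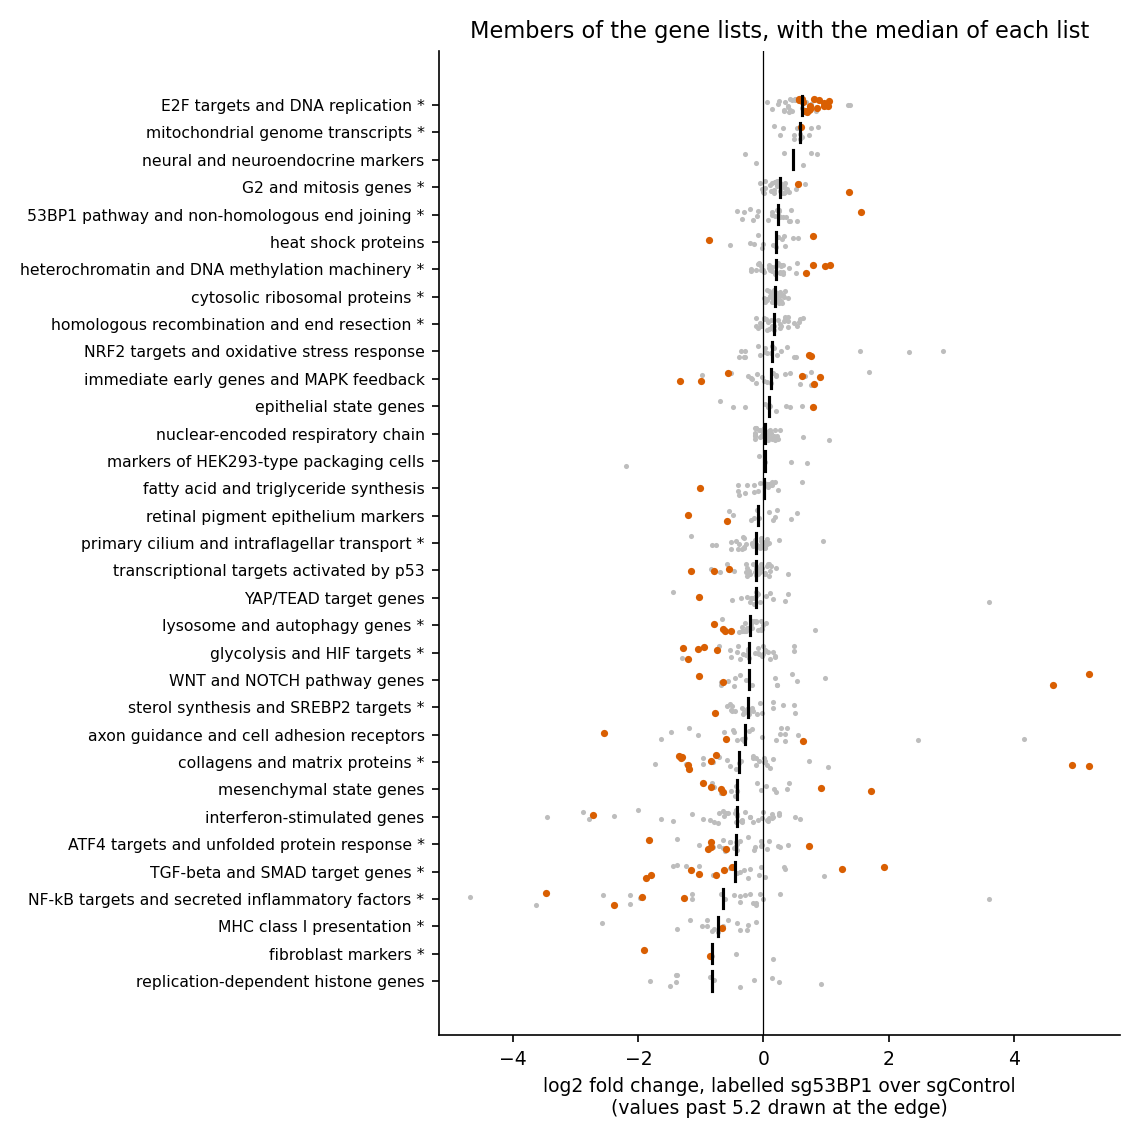
Log2 fold change, libraries labelled sg53BP1 over sgControl, of the measured members of 33 gene lists. Orange points passed an adjusted p of 0.05, grey points did not, black bars are list medians and an asterisk marks the 17 lists past a camera adjusted p of 0.05. The E2F targets have the highest median, 0.62, and values past the axis limit are drawn at its edge.

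The other lists did not pass camera. Immediate early and MAPK feedback genes had 3 called higher and 3 lower of 27 (4 and 3 adjusted over the list alone; camera adjusted p = 0.217): KLF2, KLF6 and DUSP1 rose 1.86-fold, 1.53-fold and 1.74-fold, and DUSP4, a MAP kinase phosphatase, fell 2.01-fold. KLF6 and DUSP1 lost their calls with the replicate number as a block (adjusted p = 0.0739 and 0.124). WNT and NOTCH genes had 2 called higher and 2 lower of 18 (3 and 7 adjusted over the list alone; camera adjusted p = 0.898), with a median of −0.24 and a mean of 0.41. The stem cell receptor LGR5 rose from 0.150 ± 0.128 to 3.88 ± 0.850 CPM (SD, n = 2 each), with a log2 fold change between 3.98 and 5.90 when 1 library was left out, the upper value without sgControl replicate 1. WNT7B had 0 and 2 counts against 57 and 47, a ratio of 48.1 with a 95% counting interval of 13.0 to 403, and the secreted DKK3 and WNT5B fell 2.04-fold and 1.56-fold. WNT5B lost its call with library totals (adjusted p = 0.0506) and the replicate number as a block (adjusted p = 0.0707). Axon guidance and adhesion genes had 1 called higher, PLXNA2 at 1.55-fold, and 2 lower, SEMA3D at 5.85-fold and NTM at 1.51-fold, of 27 (1 and 2 adjusted over the list alone; camera adjusted p = 0.347). PLXNA2 and NTM lost their calls with the replicate number as a block (adjusted p = 0.0766 and 0.0759), and NTM with DESeq2 size factors (adjusted p = 0.0515).

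Called members of the remaining lists were few, and those named here were chosen after their values were seen. NRF2 targets had 2 called higher of 23 (3 and 0 adjusted over the list alone; camera adjusted p = 0.0516, and 0.0455 without sg53BP1 replicate 1, 0.0454 at a mean of at least 5 CPM, 0.0299 with the DESeq2 Wald test, 0.021 with limma-voom and 0.0481 with the replicate number as a block), SLC7A11 and the quinone reductase NQO1, which rose 1.68-fold. Heat shock genes had HSPA1A 1.72-fold higher and HSPB8 1.82-fold lower of 17 (2 and 2 adjusted over the list alone; camera adjusted p = 0.173). Epithelial genes had PKP2 1.73-fold higher of 12 (camera adjusted p = 0.371), YAP targets had ANKRD1 2.05-fold lower of 22 (camera adjusted p = 0.34) and fatty acid synthesis had FADS2 2.02-fold lower of 21 (camera adjusted p = 0.74, downward, with a median of 0.01 and a mean of −0.08). Retinal pigment epithelium markers had EFEMP1 and RDH11 lower, by 2.30-fold and 1.49-fold, of 14 (camera adjusted p = 0.74). Each of the last 4 lists had the same called members adjusted over the list alone. No member was called among 36 nuclear genes of the respiratory chain (camera adjusted p = 0.243), 6 neural markers (camera adjusted p = 0.127) or 5 markers of embryonal kidney packaging cells (camera adjusted p = 0.734, upward, with a median of 0.03 and a mean of −0.22). The first 2 of these also had none adjusted over the list alone, and the kidney list had 1 lower. Of 8 blood cell markers with counts only CSF1R passed the low-count filter, at 6.54 ± 3.53 and 2.22 ± 0.150 CPM (SD, n = 2 each; edgeR adjusted p = 0.0779), so that list was not tested.

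Of 33 lists tested, 17 passed camera with its preset correlation, 7 upward and 10 downward, and none with an estimated correlation, where the smallest adjusted p was 0.56. With 2 libraries per group the estimated correlation left few degrees of freedom, so its lack of calls decides little. The rotation test fry called 0 lists in one direction (smallest adjusted p = 0.0752) and 26 for change in either direction. Lists of E2F targets, homologous recombination, heterochromatin, ribosomal proteins, NF-kB, ATF4 and TGF-beta passed camera in each of the 4 fits that left out 1 library.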

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

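The difference in TP53BP1, 1.56 on the log2 scale, kept its direction in every setting tried, between 1.38 and 1.81 with 1 library left out, and lost its call without either library labelled sg53BP1. The count of 667 genes was 654 to 991 with other scalings, the DESeq2 Wald test and limma-voom, 547 at a mean of at least 5 CPM, 1548 without the low-count filter and 368 at an absolute log2 fold change of at least 1. It ranged from 5 to 3358 with 1 library left out, because the spread then came from the other group's pair alone. Deviations of same-numbered libraries correlated at 0.03. The SD of log2 differences was 0.181 in the sg53BP1 pair and 0.488 in the sgControl pair. With so little deviation in the sg53BP1 pair, the correlation cannot tell whether replicate numbers pair the libraries. With the number as a block, 297 genes passed and the TP53BP1 call was kept (edgeR adjusted p = 0.029). The 17 lists called became 0 with an estimated correlation, 0 with directional fry, 26 with mixed fry and 12 to 17 with 1 library left out; the other settings gave 16 to 20. List medians turned sign for fibroblast markers without the low-count filter (0.015) and for interferon-stimulated genes with limma-voom (0.142) and the replicate block (0.096). Among lists not called, those of retinal pigment epithelium and fatty acid synthesis also turned at a mean of at least 5 CPM, and with 1 library left out those of p53 targets (to 0.206), kidney, epithelial, respiratory chain, YAP and fatty acid genes. With 1 library left out, medians ranged from −0.228 to 0.045 for primary cilium genes, −1.179 to 0.239 for MHC class I genes and −1.143 to 1.094 for interferon-stimulated genes, with the positive ends without sgControl replicate 1, 2 and 2; the cause was not tested. Of 74 other genes that met the rule for named genes, 50 kept their call with the replicate block, 69 with DESeq2 size factors, 70 with limma-voom, 71 with library totals, 74 with the DESeq2 Wald test, without the low-count filter or without either sgControl library, and 2 and 1 without sg53BP1 replicate 1 and 2; at a mean of at least 5 CPM, 60 of 60 tested kept it. At this depth and number of libraries, with independent genes and 1 spread for both groups, 61 of 100 simulated changes of 1 on the log2 scale were recovered.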

Other observations

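Genes outside the rule for named genes, all chosen after their values were seen, gave further differences between the groups as labelled. MECOM, a zinc-finger transcription factor of blood stem cells, had 52.4 and 57.8 CPM in the libraries labelled sgControl and 336 and 313 CPM in those labelled sg53BP1 (log2 fold change 2.56, standard error 0.13, edgeR adjusted p = 5.11e-05). GFRA1, the co-receptor of the growth factor GDNF, had 6 and 3 counts against 451 and 474 (log2 fold change 6.53, edgeR adjusted p = 5.08e-05), and the cytokine IL18 had 4 and 8 counts against 240 and 220 (edgeR adjusted p = 3.43e-04). The carboxypeptidase CPVL, the annexin ANXA3 and the aldose reductase AKR1B1 were also higher, by 5.17, 2.40 and 1.64 on the log2 scale. TERT, the catalytic subunit of telomerase with which the line was immortalised, was lower in the libraries labelled sg53BP1, at 21.4 and 20.5 against 8.41 and 10.7 CPM (log2 fold change −1.13, edgeR adjusted p = 0.0125); counts do not tell the introduced copy from the endogenous gene.

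Among single genes tied to interferon, counts are given for the libraries labelled sgControl first and those labelled sg53BP1 second. IFNL1, a type III interferon, had 23 and 15 counts against 0 and 0. It was at least 13.7-fold lower in the libraries labelled sg53BP1, against a floor of 3 counts over the group (edgeR adjusted p = 0.0164). IFNB1, the type I interferon beta, had 110 and 39 counts against 5 and 0 (edgeR adjusted p = 0.0717), and the chemokine CCL5 had 706 and 253 against 19 and 21 (edgeR adjusted p = 0.0838), so these 2 did not pass. IFNL1, IFNB1 and CCL5 were each higher in sgControl replicate 1 than in replicate 2, opposite to the list of interferon-stimulated genes. CIITA, the master regulator of MHC class II genes, was lower in the libraries labelled sg53BP1, at 10.5 and 21.5 against 3.43 and 4.94 CPM (edgeR adjusted p = 0.0469). Some genes stood out in a single library labelled sgControl: CUBN had 3434 counts and CCDC171 4607 counts in sgControl replicate 1 against 100 and 53 in replicate 2.

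All tests of the patterns below except that of chromosome loss were chosen only after the result was seen. TP53BP1 was higher in both libraries labelled sg53BP1, where its knockout is labelled. A gained chromosome segment wide enough to cover most neighbouring genes is argued against. The 20 neighbouring tested genes had a median log2 fold change of 0.078 (quartiles −0.15 and 0.22, highest 0.959). A median over these genes cannot exclude a gain of TP53BP1 with few neighbours. An exchange of the group labels and a raised transcript from an edited gene both stay open, as no value here decides between them, so the direction of every difference reported here is open as well. The other 2 ways to split the 4 libraries into pairs each gave 0 genes with edgeR (112 and 57 at an unadjusted p under 0.05) against 667 for the labelled split, and 3 splits are too few for a share under 0.05. Both other splits set the 2 close sg53BP1 libraries apart, each beside a distant sgControl library. Few calls were thus likely whatever the cause, and the 667 gain no support from them.

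The libraries labelled sgControl differed from each other in interferon-stimulated genes, with 43 of 43 members higher in replicate 2 than in both libraries labelled sg53BP1 and 32 lower in replicate 1 than in both. Depth is argued against, as the list's gap was 2.03 log2 units while the count totals differed by a ratio of 1.011. One library exchanged between the groups is argued against by the correlation of the sg53BP1 pair, 0.9937, the highest of all pairs, the next being 0.956. Whether blood cells in replicate 2 were the source of the gap could not be decided. The 8 blood markers together held 6.01 CPM there against 10.5 CPM in replicate 1, a ratio of 0.573. All MHC class I genes but PDIA3 were higher in replicate 2, HLA-B at 1391 against 255 CPM and B2M at 3806 against 1864 CPM. CSF1R carried most of the marker sum and was therefore left out of the ratio that decides. The other 7 markers, at 33 against 24 counts, gave a ratio of 1.358 (95% counting interval 0.779 to 2.402). That interval holds both a fall and a rise, so blood cells stay possible. A different state of the cells labelled sgControl, such as a differing response to interferon, and a library from an outside sample were not tested.

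Some genes were silent in both libraries labelled sgControl: 12 genes had at most 1 count in each and at least 50 in each library labelled sg53BP1 (MBNL3, ALDH3A1, NRK, CD180, STON2, MPZL2, ZNF704, GNGT2, LRRN1, KLHDC7A, MFAP5 and H2AJ), against 0 genes the other way. Between the libraries labelled sgControl themselves 14 genes were on in one and off in the other, against 25 to 28 for each pair from different groups and 0 for the sg53BP1 pair. Depth is argued against, because no library labelled sgControl had less than 0.917 times the count total of one labelled sg53BP1. Loss of chromosome segments is argued against as the cause for the set, because 118 neighbouring tested genes had a median log2 fold change of 0.008 (quartiles −0.36 and 0.26). The highest neighbour reached 8.549, and a median pooled over all loci cannot exclude a loss at single ones. An effect of the edit itself and a separate derivation of the cells were not tested and stay open, and the labels do not say whether single cells were cloned.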
